A study of Mus musculus with 2 samples.

How the data were processed

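The series holds total RNA sequencing of mouse lung at embryonic day 15.5, in 2 biological replicates that form a single group. Per the labels, replicate 1 was made from lungs of 78 embryos and replicate 2 from lungs of 62 embryos of the B6NCrl strain, with male and female embryos pooled. Each library has its own biological replicate number in the labels, so the spread between libraries takes in the spread between pools of embryos. Each pool has a single library, so differences of dissection, extraction or library preparation cannot be told apart from it. RNA was extracted with the mirVana method, molecules longer than 200 nt were kept, 10 ng of RNA entered each library and spike-in sequences were added, all per the labels' protocols. The protocol documents named in the labels include the manual of a SMARTer Ultra Low kit.

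For each library the authors deposited a table of genes and a table of transcripts. The expected counts are estimated reads per feature, per the file headers, and need not be whole numbers. The deposited TPM values, per the file headers, are transcript levels scaled to the same total over all features of a table, spike-in sequences included. The deposited FPKM values are fragments per kilobase of effective length scaled to library size, per the file headers. The deposited transcript tables also give the percent of each gene's TPM that a transcript holds. Per the file headers the tables further hold posterior mean values and an interval of the TPM, whose level is not stated there. The interval is placed around the posterior mean TPM: among genes over 1 TPM, the TPM itself lay outside it for 587 genes in replicate 1 and 667 in replicate 2, and the posterior mean for 0 in either. The program that made the tables, its version and the use of strand in counting are not given in the sources used here. The genome build mm10 and the annotation GENCODE M4 are named in the deposited text that describes the files.

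Each gene table lists 69691 features. Of these, 43346 have an Ensembl gene identifier, 97 are spike-in sequences and 26248 are short numbered features with a median length of 73 nt that name no gene. The numbered features stayed out of library sizes and comparisons, and held 71 reads in replicate 1 and 66 in replicate 2. Gene names, types and positions were taken from GENCODE M21 on the same build, GRCm38, by identifier, and 97.96% of the Ensembl identifiers were matched. The 884 unmatched identifiers held 0.203% of the count in replicate 1 and 0.201% in replicate 2. Positions are 1-based and exist for names in M21, while the counting used the older annotation.

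Replicate 1 had 40395849.9 estimated reads in all and 39530296.9 in genes, and replicate 2 had 36601054.1 and 35733530.1. At these depths 3 reads, the upper limit that a count of 0 allows, equal 0.113 TPM in replicate 1 and 0.122 TPM in replicate 2 for a gene with an effective length of 1 kb. The floor was computed for each listed gene and library from its own effective length. Intervals cover counting and read assignment only and floors counting only, since reads without molecular identifiers are not independent molecules. The counts of the libraries differed by more than sampling noise, with a chi-square of 6.66 per degree of freedom over 19397 genes, so they were not a single library deposited again.

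A gene was called detected at 1 TPM or more in both libraries. The log2 ratio of replicate 2 over replicate 1 was taken after scaling by TMM (edgeR 4.0.16, R 4.3.3), with normalization factors of 1.01 and 0.989. Expected counts were rounded to whole numbers for edgeR and DESeq2. The TMM scaling put a shift of 0.07 (log2) on the TPM of replicate 2, and DESeq2 size factors put on one of the same rounded size. The spread between replicates was given as the SD of the log2 ratio in bins of mean TPM, beside the SD that counting alone gives, and as the biological coefficient of variation from the common dispersion of edgeR with an intercept only. Pearson and Spearman correlations were computed across genes on log2(TPM + 1).

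Genes were called apart between the libraries when their mean TPM was at least 5, their scaled TPM differed 2-fold or more and their deposited intervals did not overlap. Each of 45 gene lists for cell types, neighbouring organs, pathways and processes was described by the median TPM of its members. Of the 557 different genes in them, 1 symbol (Ahsp) matched no feature name and was not analysed here. For 43 lists with 3 or more members over 1 TPM, the median log2 ratio was set against 10000 random lists of the same size, matched on mean level in 20 bins. These percentiles describe the libraries at hand and are no test of a condition. Within a list, genes are called different only where both libraries gave the same order and the deposited intervals overlapped in neither. The pairs of genes set against each other were chosen after their values were seen. With a single group of 2 no test between conditions exists, and an exact permutation of 2 values against 2 cannot go below p = 0.333, so no p-value is given.

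The gene lists, the design, the rule for named genes and the alternatives to try were fixed before the data were examined. Named genes are the 20 protein-coding or long noncoding nuclear genes with the highest mean TPM, the 3 highest and the lowest member of each list, members not detected, and the 10 genes with the largest ratio each way among genes apart. Other list members appear as values where a group is described, and isoforms are given for 12 genes chosen in advance and for the 5 most abundant genes whose leading transcript differed. Some genes that this rule takes in are not reported here. Genes named outside this rule are said to be so. Genes with near-identical copies, such as the globin, histone, T cell receptor and mitochondrial genes, and antisense or overlapping genes are uncertain, because their reads could be split between copies.

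The calculations were tested on simulated data drawn from the real means and library sizes of these 2 libraries over 43346 genes. The simulation had no read assignment, so count ratios and intervals from counting alone stood in for the scaled TPM and the deposited intervals. In that setting the rule for genes apart found 100% of 50 genes changed 6-fold, 98% of 100 genes changed 3-fold and 4% of 50 genes changed 1.5-fold. It took in 1 of 11061 unchanged genes. These shares do not cover the error of read assignment in the real libraries. Of 400 random lists of 10 genes, 4.75% lay outside the central 95% of matched lists. Such lists are random draws themselves, so this checks the calculation only. Of 100 lists shifted by 0.25 (log2), 91% lay outside. The shifted lists held genes with a mean of 5 TPM or more, while the real lists take members from 1 TPM. The 91% therefore does not cover lists with lower genes. A simulated biological coefficient of variation of 0.1 came back as 0.0985, and as 0.138 with 200 changed genes among the rest.

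Alternatives covered the scaling (DESeq2 1.42.0 size factors, or none), pseudocounts, minimum levels, posterior mean TPM, FPKM, an exact binomial test with Benjamini-Hochberg adjustment at 0.05, removal of a lowess trend on transcript length (span 0.3) and leaving out each replicate. Further tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Random draws used a fixed seed, and bootstrap intervals used 300 resamples of genes, or 2000 for gene lists of the closing tests.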

Results

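Total RNA was sequenced from whole mouse lung at embryonic day 15.5, a time when the airway tree is still branching. The single group held 2 libraries, replicate 1 from a pool of 78 embryos and replicate 2 from a pool of 62. Their depths were 40395849.9 and 36601054.1 estimated reads. The design implies a catalogue of the genes expressed in the tissue and a comparison of the replicate pools. Levels are the mean TPM ± SD of the libraries (n = 2), a gene counts as detected from the minimum of 1 TPM in both libraries, positions are on GRCm38, and values per library are given as replicate 1 and then replicate 2.

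The question of the catalogue is which genes the embryonic lung expressed and at what level. Among protein-coding and long noncoding nuclear genes, globin genes of the red blood cells led, followed by Sftpc, the surfactant protein gene of the distal lung epithelium. Hba-a2 (ENSMUSG00000069917.7; chromosome 11, 32296489 to 32297298) reached 18761 ± 1011 TPM, Hbb-bs (chromosome 7, 103826534 to 103828096) 9503 ± 145, Hba-a1 (chromosome 11, 32283511 to 32284465) 6897 ± 434 and Hbb-bt (chromosome 7, 103812524 to 103813996) 6660.3 ± 502. Sftpc (ENSMUSG00000022097.3; chromosome 14, 70520949 to 70524081) stood at 6372 ± 719 TPM. Cytoskeletal and housekeeping genes came next, with Actb at 5971 ± 110.4, Ppia at 5217 ± 25.3, Ftl1 at 4417 ± 23.5 and Eef1a1 at 3949 ± 53.1. The actin-binding Tmsb4x reached 3789.8 ± 108, the replication-dependent histone gene Hist1h2ap 3684 ± 232 and the nuclear noncoding RNA Malat1 3430.1 ± 431. Close-lying features annotated as long noncoding on chromosome 17 also ranked high, Gm42418 (39846958 to 39848788) at 3883 ± 486 and Gm26917 (39843013 to 39846341) at 2959 ± 4.23. Which RNA their reads come from was not tested, so their type rests on the annotation alone. The remaining members of the 20 most abundant genes of these kinds were Rpl41 (3352 ± 211), Ubb (2648 ± 35.6), Ptma (2411 ± 55.5), Hmgn2 (2383 ± 64.2), Actg1 (2217 ± 24.8) and Rps19 (2193 ± 199). Features of other kinds are left out of this order. Among them, named after their values were seen, the 7SL RNA copies Rn7s1 and Rn7s2 stood at 12908 ± 950.2 and 12908 ± 949.5, between Hba-a2 and Hbb-bs, with wide intervals that overlap. The alpha and beta globin copies share sequence, so the split between Hba-a1 and Hba-a2 and between Hbb-bs and Hbb-bt is uncertain.

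In both libraries 14583 genes had 1 TPM or more. They comprised 13038 protein-coding genes, 685 long noncoding genes, 524 pseudogenes, 244 genes of other types and 92 that are not in the newer annotation. At 10 TPM or more there were 9063 genes, at 100 TPM or more 1643 and at 1000 TPM or more 94. Protein-coding genes held 93.5% and 93.1% of the estimated count. Mitochondrial features held 2.61% and 2.62% of the TPM. This share leaves out the chromosome 1 pseudogenes Gm28437, Gm28661 and Gm29216 (7156 ± 238, 2474 ± 193 and 2251 ± 90.4 TPM), which match mitochondrial genes nearly fully, and may be too low by up to their part. Of the 557 genes in the fixed lists, 479 were detected.

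Epithelial genes were abundant. All 12 general epithelial genes were detected, with a list median of 83.1 ± 4.65 TPM. Krt8 led them at 299 ± 26.8, followed by the adhesion molecule Epcam at 244 ± 3.26 and Krt19 at 220.0 ± 7.95. Nkx2-1 (ENSMUSG00000001496.11; chromosome 12, 56531958 to 56536908), the transcription factor that marks lung epithelium, reached 72.6 ± 2.16, and Elf5 was lowest at 4.4 ± 1.02. The 8 distal tip genes were all detected, with a median of 51 ± 0.0177. Id2 reached 351 ± 16.3, the FGF target Etv5 141 ± 0.863 and Bmp4 55.9 ± 4.44. Sox9, a regulator of the tips, stood at 53.7 ± 0.141, and Etv4 was lowest at 10.7 ± 0.198. The airway list had 9 of 10 members detected and a median of 8.23 ± 2.17. Its highest member was the secretory cell gene Scgb3a2 at 404 ± 50.9, followed by Cyp2f2 at 38.9 ± 4.82 and Foxj1, the regulator of motile cilia, at 17.8 ± 0.163. Scgb1a1, the club cell secretoglobin, was low at 5.82 ± 2.13, and Muc5b was not detected at 0.20 ± 0.0141. The ratio of Sox9 to the airway regulator Sox2 was 15.3 ± 2.44, and that of Scgb3a2 to Scgb1a1 was 76.2 ± 36.7, with separate intervals in both libraries.

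Genes of the alveolar cell types were already present but uneven in level. Among type 2 genes 9 of 10 were detected, with a median of 23.9 ± 4.65 TPM, and Sftpc stood far above the rest. The phospholipid enzyme gene Lpcat1 followed at 77.3 ± 7.79, Sftpa1 at 72.3 ± 15.5 and Sftpb at 69.8 ± 12.5. Sftpc exceeded Sftpb 91.9 ± 6.19-fold and Sftpa1 89.1 ± 9.1-fold. Sftpd lay under the minimum at 0.665 ± 0.233. For type 1 genes 8 of 9 were detected, with a median of 21.8 ± 3.32. Cav1, also expressed by endothelium, led at 412 ± 48, then Ager at 187 ± 31.5 and Emp2 at 71.8 ± 8.89. The water channel gene Aqp5 stood at 1.06 ± 0.269 and missed 1 TPM in replicate 2. Most neuroendocrine genes were low, 7 of 10 detected with a median of 2.0 ± 0.629. Uchl1 reached 55.8 ± 4.53, Ddc 13.5 ± 0.523 and the peptide gene Grp 3.69 ± 0.544. Scg5 at 1.07 ± 0.332, which missed 1 TPM in replicate 2, and Insm1 at 0.11 ± 0.0283 were not detected, and Nkx2-2 had a value of 0 in both libraries, with deposited intervals that reach up to 0.752 and 0.805 TPM.

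The mesenchymal list had the highest median among lung cell types other than blood, in both libraries. All 12 mesenchymal genes were detected, with a median of 104 ± 1.24 TPM. The collagen genes Col3a1 (1311 ± 67.5; chromosome 1, 45311538 to 45349706) and Col1a1 (1030.3 ± 45.2) led, followed by Vim at 735 ± 12.3. Among regulators, Tcf21 stood at 242 ± 9.74, Foxf1 at 129.8 ± 2.78 and Tbx4 at 67.5 ± 1.12. Tbx4 exceeded Tbx5 1.93 ± 0.137-fold. Fgf10, the growth factor that draws out the tips, was the lowest member at 14 ± 0.495. Smooth muscle genes were all 10 detected, with a median of 60.3 ± 0.0566. Acta2 reached 777 ± 70.6, Actg2 161 ± 21.9 and Tagln 96.7 ± 7.13, while Lmod1 was lowest at 3.87 ± 0.12. Acta2 exceeded the smooth muscle myosin gene Myh11 14.8 ± 0.855-fold. The 8 pericyte genes were detected at a median of 16.6 ± 0.693, from Cox4i2 at 65.6 ± 4.12, Pdgfrb at 46.3 ± 0.636 and Higd1b at 22.9 ± 3.66 down to Abcc9 at 3.78 ± 0.297. Mesothelial genes, of the covering layer, had 7 of 7 detected and a median of 12.3 ± 2.18, with Upk3b at 31.9 ± 4.96, Aldh1a2 at 28.6 ± 4.19, Msln at 12.7 ± 2.67 and Bnc1 at 1.35 ± 0.127. Cartilage genes of the airway wall had 5 of 7 detected, led by Hapln1 at 18.5 ± 0.495, Col2a1 at 16.7 ± 0.806 and Col9a2 at 10.6 ± 0.0919, with a median of 9.44 ± 0.41. Matn1 at 0.52 and 0.21 TPM per library and Acan at 0.335 ± 0.0636 lay under the minimum.

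Vascular and blood cells were well represented. All 10 endothelial genes were detected, with a median of 56.5 ± 2.43 TPM. Cldn5, a tight junction gene, reached 102 ± 5.24, Pecam1 95.5 ± 5.4 and Tie1 72.2 ± 0.721, and Erg was lowest at 9.49 ± 1.33. Lymphatic genes included Lyve1 at 43.2 ± 4.19, Mmrn1 at 18.8 ± 0.566, Flt4 at 7.7 ± 0.184 and the lymphatic regulator Prox1 at 1.58 ± 0.163. Reln at 1.22 ± 0.375 missed 1 TPM in replicate 2, and the lymphatic median was 7.7 ± 0.184. Pecam1 exceeded Prox1 60.4 ± 2.79-fold. The 12 macrophage and leukocyte genes were all detected, with a median of 12.3 ± 0.354. Tyrobp stood at 44.8 ± 3.17, the complement gene C1qb at 41 ± 3.01, Fcer1g at 39.2 ± 0.467 and Itgam, the lowest, at 1.32 ± 0.276. Erythroid genes had 11 of 12 detected and a median of 139 ± 20.5. The globins together held 4.28% ± 0.239 of the TPM (SD, n = 2), and 1.41% of the estimated count. The embryonic beta-like gene Hbb-y reached 828 ± 253 and exceeded Hbb-bh1 95 ± 1.26-fold, and the ratio of embryonic to adult globin was 0.0196 and 0.0281. Epb42 lay under the minimum at 0.925 ± 0.0495. Neural genes had 5 of 8 detected at a median of 1.98 ± 0.421, led by Erbb3 at 18.6 ± 1.03, Tubb3 and Elavl4 at 2.69 ± 0.552, with Sox10 at 0.66 ± 0.17 and Foxd3 at 0.095 ± 0.0212 under the minimum. Tubb3 lay apart between the libraries, at 9.68 and 3.84 TPM.

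**Figure D1:**
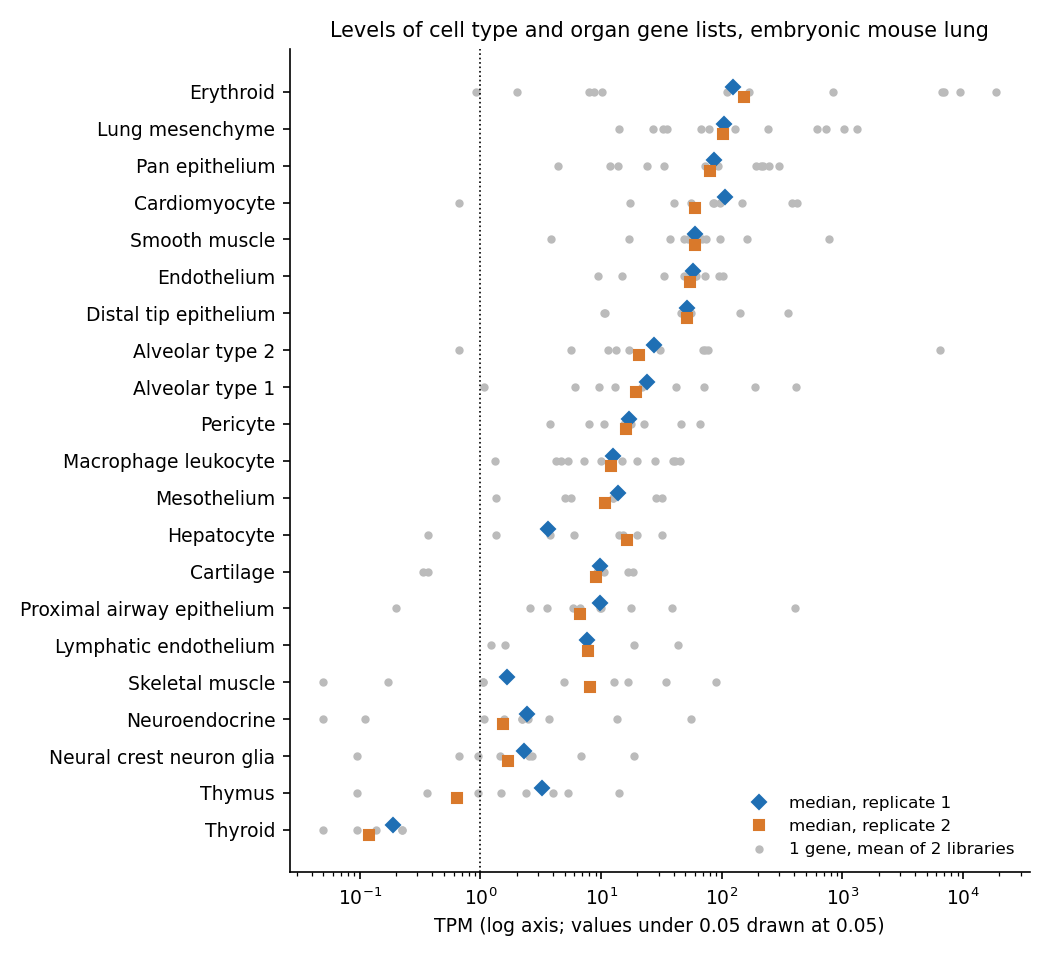
TPM on a log axis of the genes of each cell type and organ list, with the list median of replicate 1 (diamonds) and replicate 2 (squares), each grey point a gene's mean over the 2 libraries, values under 0.05 drawn at 0.05 and the dotted line at 1 TPM. The medians of most lung cell types lie close together between libraries, while those of the hepatocyte, thymus and skeletal muscle lists lie apart. Those of the cardiomyocyte list lie apart to a lesser degree (106 and 59.6 TPM).

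Components of the growth factor pathways that shape the lung were nearly all expressed. The 9 hedgehog genes were detected at a median of 15.8 ± 0.283 TPM, with the antagonist Hhip at 74.3 ± 2.18, Smo at 31.6 ± 1.44 and Sufu at 27.3 ± 1.44. The epithelial ligand gene Shh stood at 10.7 ± 0.424, below its receptor gene Ptch1, which exceeded it 2.12 ± 0.0625-fold. Among FGF genes 13 of 14 were detected, with a median of 14.7 ± 1.2. The receptor gene Fgfr2 (chromosome 7, 130162451 to 133123350) led at 141 ± 11.3, 5.14 ± 0.423-fold above Fgfr1, followed by Dusp6 at 59.1 ± 0.714 and Fgfr3 at 52.1 ± 3.99. Fgf10 exceeded Fgf9 1.98 ± 0.145-fold, the intervals of Fgf18 and Fgf7 overlapped, and Fgf2 at 1.06 ± 0.453 missed 1 TPM in replicate 2. All 19 WNT genes were detected at a median of 12.1 ± 1.31, with Ctnnb1 at 394 ± 0.806, the mesenchymal ligand Wnt2 at 78.1 ± 5.27, the epithelial ligand Wnt7b at 45.7 ± 0.205 and Wnt4 lowest at 1.56 ± 0.0141. For BMP and TGF-beta signalling 22 of 23 genes were detected, with a median of 18.3 ± 0.226. Id3 stood at 432 ± 21.3, Id1 at 117 ± 6.36 and Tgfb2 at 72.7 ± 4.04, and Bmp4 exceeded Bmp2 16.3 ± 0.355-fold. The BMP antagonist Grem1 lay under the minimum at 0.115 ± 0.00707.

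Among Notch genes 13 of 14 were detected at a median of 14.1 ± 0.166 TPM, led by Hes1 at 40.5 ± 1.04, Notch2 at 28.1 ± 0.693 and Heyl at 25.3 ± 0.156. Hes5 lay under the minimum at 0.58 and 0.24 TPM per library. Retinoic acid genes had 12 of 13 detected and a median of 15.8 ± 0.41, with Dhrs3 at 43.8 ± 1.03 and the receptor Rarg at 36.8 ± 0.198. Cyp26a1, which breaks down retinoic acid, lay under the minimum at 0.43 and 0.12 TPM per library. The 14 VEGF and PDGF genes were detected at a median of 23.8 ± 1.47, with Nrp1 at 67.4 ± 3.79, Kdr at 48.6 ± 3.54 and Pdgfrb at 46.3 ± 0.636. Vegfa was the lowest of them at 4.78 ± 0.537, and Vegfd exceeded it 8.92 ± 1.56-fold. The 14 genes of the insulin-like growth factor system were detected at a median of 49.4 ± 1.67, with Igf2 at 453 ± 4.51, Igfbp4 at 425 ± 18.3, Igfbp2 at 295 ± 6.46 and Igfbp3 lowest at 12.1 ± 1.9. Igf2 exceeded Igf1 7.15 ± 0.295-fold. The 10 Hippo genes were detected at a median of 20.4 ± 1.44, with Tead2 at 155 ± 0.297, Ccn1 at 49.1 ± 0.0141, Yap1 at 29.3 ± 0.226 and Tead4 lowest at 4.45 ± 0.255.

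Hox genes, which mark position along the body axis, were expressed from the anterior and middle parts of the A and B clusters. Of 39 Hox genes 14 were detected. Hoxb5 (chromosome 11, 96303336 to 96306121) stood at 42.2 ± 4.53 TPM, Hoxa5 (chromosome 6, 52201754 to 52204587) at 40.8 ± 0.587 and Hoxb2 at 32 ± 1.18. Hoxa5 exceeded its neighbour Hoxa4 11.8 ± 0.0949-fold. It exceeded Hoxa9 294-fold and 161-fold per library (228 ± 93.9), but Hoxa9 was not detected, so the size of this ratio is uncertain. Hoxc4 at 1.25 ± 0.0354 was the C cluster member that reached 1 TPM in both libraries, and the D cluster had none. The highest of the undetected genes were Hoxb8 at 0.81 ± 0.0707, Hoxc5 at 0.53 ± 0.099 and Hoxd8 at 0.38 ± 0.0707. Hoxc11, Hoxd13 and Hoxb13 had a value of 0 in both libraries, which allows up to 0.059 and 0.0634, 0.0476 and 0.0512 and 0.0538 and 0.0579 TPM.

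**Figure D2:**
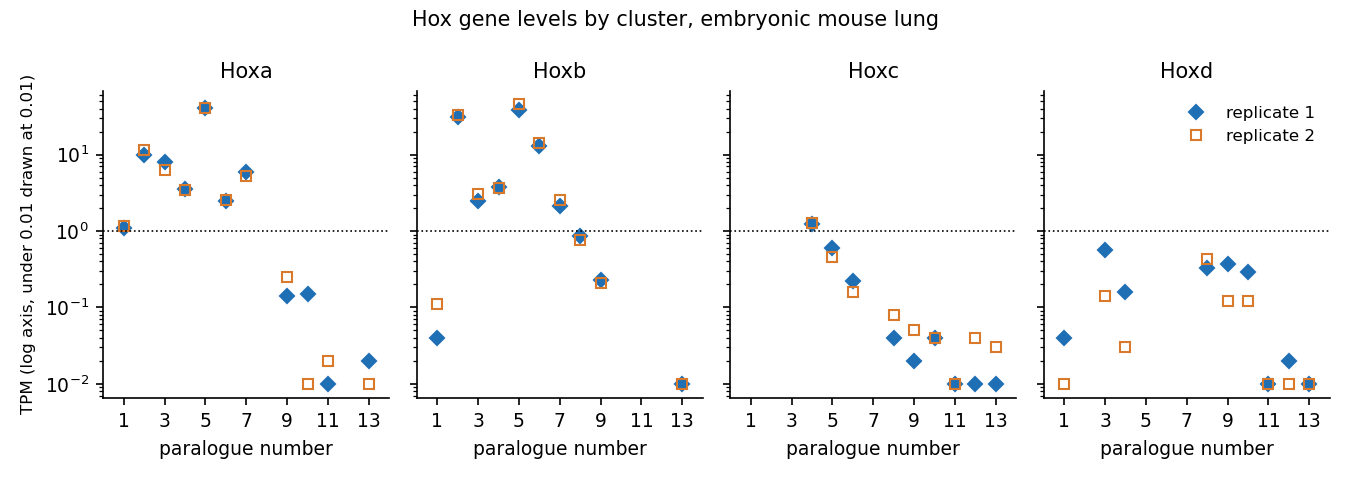
TPM on a log axis of each Hox gene by paralogue number in clusters A to D, in replicate 1 (filled diamonds) and replicate 2 (open squares), values under 0.01 drawn at 0.01 and the dotted line at 1 TPM. Hoxa5, Hoxb2 and Hoxb5 stand highest, and no D cluster gene reaches 1 TPM.

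Imprinted genes, which can be expressed from the copy of a single parent, were abundant. The values do not tell the parental copies apart. In this list 24 of 26 were detected, with a median of 64.9 ± 2.56 TPM. Gnas reached 1721 ± 49.6, Mest 1280.4 ± 44.7 and Nnat 584 ± 7.13. The growth regulators Igf2 and H19 stood at 453 ± 4.51 and 373 ± 13, a ratio of 1.22 ± 0.0544. Zim1 at 1.19 ± 0.438, which missed 1 TPM in replicate 2, and Usp29 at 0.085 ± 0.00707 were not detected. Cell cycle genes were all 18 detected, with a median of 179 ± 3.49, led by Cdk1 at 532 ± 0.813, Birc5 at 303 ± 7.88 and Ccnb1 at 247 ± 3.46, and lowest for Mki67 at 46.6 ± 1.34. The 12 elastic fibre genes were detected at a median of 124 ± 7.9, with Mfap4 at 920.0 ± 68.5, Mfap2 at 419.8 ± 0.679, the elastin gene Eln at 406 ± 21.6 and Mfap5 lowest at 15 ± 0.481. Basement membrane genes were all 18 detected at a median of 61.9 ± 2.91. Their leaders were Col4a1 at 253 ± 15.7, Col4a2 at 104 ± 3.06 and Lamb1 at 102 ± 5.03, and Lama1 was lowest with 2.05 TPM in both libraries. Col4a1 exceeded Col4a3, a chain of the later alveolar basement membrane, 62.1 ± 6.03-fold.

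The comparison of the replicate pools asks how far the libraries differed. Among the lists, those of the liver, of the thymus and of heart and skeletal muscle differed most. Among lists of lung and blood cell types the largest shift was 0.45 (log2), of the erythroid list. Liver genes were higher in the replicate 2 library: Serpina6 7.87-fold (steroid-binding globulin; 1.2 and 8.99 TPM), Afp 5.29-fold (10.7 and 53.6), Alb 5.08-fold (4.82 and 23.3), Apoa1 4.68-fold (5.61 and 25), Apoa2 4.15-fold and Ahsg 4.01-fold. Genes of ventricular heart muscle or skeletal muscle were also higher there, Myl2 4.87-fold (25.8 and 119), Myl3 3.68-fold, Myh7 2.81-fold and Acta1 3.62-fold. T cell genes were higher in the replicate 1 library: Trbc2 7.0-fold (38.2 and 5.2), Cd3e 5.89-fold (9.22 and 1.49), Trbc1 5.07-fold, Gzma 4.6-fold, Cd3g 4.47-fold, Tcrg-C1 4.19-fold and Tcrg-C2 3.62-fold.

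Bpifa1 (ENSMUSG00000027483.7; chromosome 2, 154142880 to 154149219), a secreted protein gene of the upper airway, showed the largest ratio toward replicate 1, 8.07-fold (15.4 and 1.82 TPM). Sprr2a2, of squamous epithelium, and H2-Ab1, of antigen-presenting cells, were 3.52-fold and 3.48-fold higher in replicate 1. In all, 40 of 11261 genes with a mean of 5 TPM or more lay apart (0.355%), 27 higher in replicate 1 and 13 in replicate 2. Under an exact binomial test of the reads in place of the intervals the number was 62, and it was 157 with a minimum mean of 1 TPM and 320 with none, each including the 40. These counts compare 2 libraries and say nothing of a condition. Trbc1 and Trbc2, Tcrg-C1 and Tcrg-C2, Sprr2a2 and its relatives, and Myh6 and Myh7 have near copies, so their single values are uncertain.

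**Figure D3:**
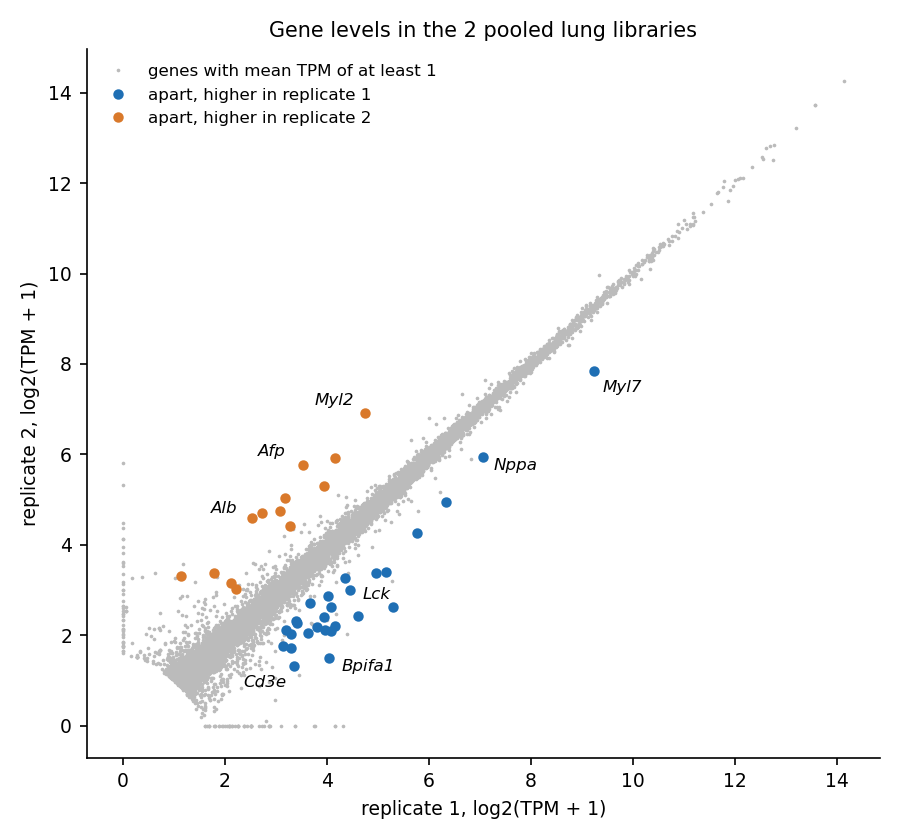
Each gene's log2(TPM + 1) in replicate 1 (x axis) and replicate 2 (y axis), for genes with a mean of 1 TPM or more, with the 27 genes apart and higher in replicate 1 in blue and the 13 higher in replicate 2 in orange. Genes at 0 TPM in a single library lie along the axes, and their intervals overlap, so they are not among the 40.

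The fixed lists of these organs shifted as well. The hepatocyte list had a median log2 ratio of 2.35 (replicate 2 over 1), with 7 of 7 members higher in replicate 2 and random lists at -0.16 to 0.11. Of its 8 genes 6 were detected, led by Afp, Apoa2 and Apoa1, while Fgb at 0.41 and 2.28 and Apob at 0.070 and 0.67 TPM were not. The thymus list had a median of -2.26 (random lists -0.32 to 0.19), with 5 of 5 members lower in replicate 2. Lck stood at 21.1 and 6.97 TPM and the pre-T cell receptor gene Ptcra at 6.89 and 1.06, while Psmb11 at 3.98 and 0.79, Rag1 at 2.46 and 0.50, Foxn1 at 1.6 and 0.30, Cd8a at 0.67 and 0.050 and Dntt at 0.15 and 0.040 (intervals up to 0.302 and 0.157) did not reach 1 TPM in both. Cardiomyocyte genes, atrial ones among them, had a median of -0.93 (random lists -0.02 to 0.10), with 9 of 9 lower in replicate 2. Myl7 stood at 609 and 228 TPM, Actc1 at 429 and 339, Tnnt2 at 160.0 and 132 and Nppa at 132 and 60.5, and Ryr2 lay under the minimum at 0.79 and 0.55. The skeletal muscle list had a median of 1.75 (random lists -0.15 to 0.11) over 7 members, or 1.03 with pseudocount 1. Of them Tnni1 was lower in replicate 2 at 98.8 and 81.7 TPM and Ckm was near equal at 34.6 and 34.6. Tnnc2 and Mylpf, of fast muscle, stood at 1.66 and 8.1 and at 11.4 and 14, while Myh3 at 0.50 and 1.6, Myog at 0.35 and 1.75, Myod1 at 0.11 and 0.23 and Pax7 at 0.030 and 0 (intervals up to 0.108 and 0.0817) did not reach 1 TPM in both. The thyroid genes Slc5a5 at 0.21 and 0.24, Tg at 0.30 and 0.15, Tshr at 0.15 and 0.12 and Pax8 at 0.19 and 0 TPM (intervals up to 1.2 and 0.864) were not detected. The interval of Pax8 in replicate 1 takes in 1 TPM.

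Lists of lung and blood cell types shifted less. Type 2 genes had a median log2 ratio of -0.28 (random lists -0.06 to 0.09; 8 of 9 lower in replicate 2) and type 1 genes -0.24 (random lists -0.08 to 0.10; 9 of 9). Sftpc itself was 6881 and 5864 TPM and Ager 209.6 and 165. Also lower in replicate 2 were the mesothelial (-0.25), neuroendocrine (-0.40), airway (-0.17), ion and fluid transport (-0.14), general epithelial (-0.05), endothelial (-0.05) and mesenchymal (-0.01) lists. Higher in replicate 2 were the erythroid (0.45), Y-linked (0.22), replication-dependent histone (0.18), smooth muscle (0.14), Hox (0.12), retinoic acid (0.09) and WNT (0.08) lists. The imprinted and mitochondrial lists lay at medians that round to 0 and just under their random ranges. In all, 22 of 43 lists lay outside the central 95% of random lists. Chance would give 2.15 for separate lists of genes that vary independently. Members of a list can move together, and some lists share genes, such as Hhip, so the excess over 2.15 is no test. The airway shift was inside the random range with all members included (-0.10), the endothelial shift was with the length trend removed (-0.04), and the imprinted shift was under 4 alternatives. Several shifts outside the range depend on the setting in size. With pseudocount 1 the neuroendocrine shift was -0.20 and the Hox shift 0.07, and with the length trend removed the histone shift was 0.09. Without scaling of the TPM, an alternative chosen after seeing the data, the retinoic acid shift was 0.00 and inside the random range, and the WNT shift 0.01. There the Hox shift was 0.07, the histone shift 0.10, and the general epithelial, mesenchymal and transport shifts -0.11, -0.09 and -0.24. The endothelial shift was inside there at -0.10, and the neural one outside at -0.42. Other lists came to lie outside the range: glucocorticoid with pseudocount 1 (-0.07), hypoxia with the length trend removed (0.10) and untailed noncoding with all members (0.16).

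The lists inside the random range were the distal tip (0.07), pericyte (-0.05), lymphatic (0.01), macrophage and leukocyte (-0.07), neural (-0.26) and cartilage (0.02) genes. The same held for hedgehog (-0.01), FGF (0.02), BMP and TGF-beta (-0.01), Notch (0.04), VEGF and PDGF (0.03), insulin-like growth factor (-0.02) and Hippo (0.08) genes. It held too for cell cycle (0.06), elastic fibre (0.05), basement membrane (-0.02), glucocorticoid (-0.07), immediate early (-0.01), hypoxia (0.09), polyadenylated histone (0.11) and untailed noncoding (0.14) genes.

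**Figure D4:**
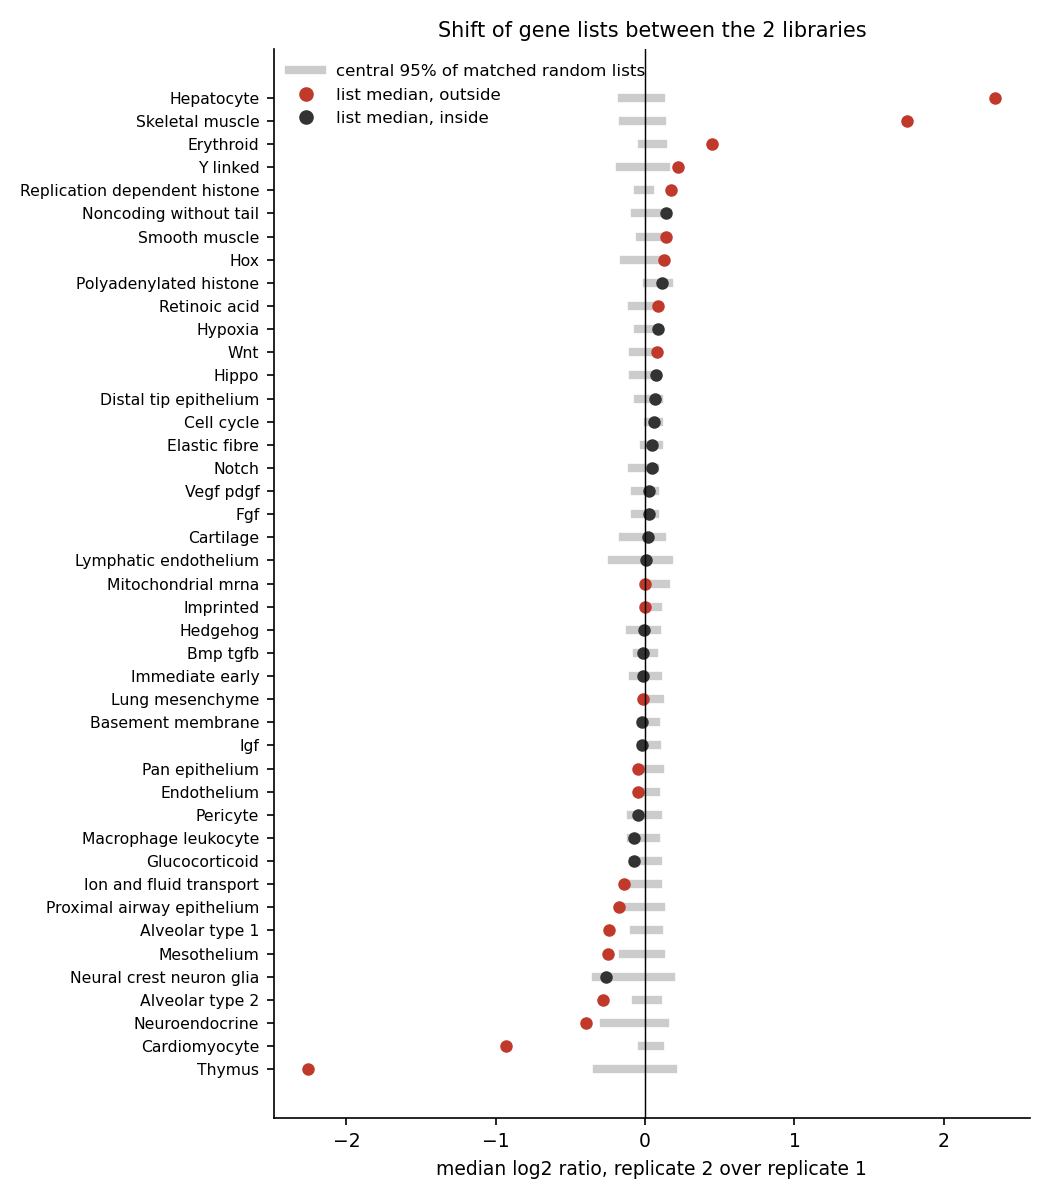
Median log2 ratio of replicate 2 over replicate 1 of each of 43 gene lists (points), with the central 95% of 10000 matched random lists as grey bars and lists outside it in red. The hepatocyte list lies highest at 2.35 and the thymus list lowest at -2.26.

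Across 15152 genes with a mean of 1 TPM or more, the libraries had a Pearson r of 0.987 on log2(TPM + 1) and a Spearman rho of 0.989, where genes are not independent replicates. The SD of the log2 ratio was 0.56 for 5808 genes at 1 to 10 TPM, 0.16 for 7560 genes at 10 to 100 TPM and 0.09 for 1688 genes over 100 TPM. Genes at 0 in a single library, 92 and 3 in the lower bins, are left out. Counting alone gives 0.36, 0.07 and 0.03, and counting with read assignment 0.77, 0.09 and 0.14. These are root mean squares over genes, which a few genes can raise. With read assignment they exceed the SD seen at 1 to 10 and over 100 TPM, so they do not divide the spread into sources. The half-width of the central 68% of log2 ratios was 0.27, 0.09 and 0.07, and the median SD from counting 0.15, 0.05 and 0.02. Of genes with a mean of 10 TPM or more, 99.2% lay within 1.5-fold. The biological coefficient of variation, which takes in library preparation as well as the pools, was 0.0745 over 17192 genes. The log2 ratio was weakly related to transcript length across genes, with a Spearman rho of -0.140.

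Transcript tables gave the share of each isoform in its gene. Nkx2-1 was led by its 2-exon transcript ENSMUST00000178477.4, with 91.8% ± 2.13 of the gene's TPM, and Pkm by Pkm-201, with 93.7% ± 0.311. Tnc-204 held 66.4% ± 6.96 of the TPM of its gene, Cd44-207 56.1% ± 0.82, Vegfa-211 49.2% ± 1.4, the leading Ctnnd1 transcript 47.4% ± 0.587, Wt1-205 38.5% ± 2.68, Tpm1-213 37.1% ± 0.891 and Fgfr2-217 27.5% ± 0.17. For Fn1 the leader differed by point estimate, Fn1-201 (33.5% ± 0.615) in replicate 1 and the retained intron transcript ENSMUST00000185408.2 (33.3% ± 0.834) in replicate 2, with overlapping intervals. The intervals of the leading and the next transcript of Vegfa and of Wt1 overlapped too, so their leaders are uncertain. Sftpc and Eln had 1 transcript each. Of 6837 genes with a mean of 10 TPM or more and at least 2 transcripts, 2491 (36.4%) were led in both libraries by a transcript with 80% or more of the TPM. By point estimate the leading transcript differed between libraries for 386 genes (5.65%), the most abundant being Tra2b, Nisch, Commd1, Sf3b1 and Fermt2, and for 0 of them were the intervals separate. Shares of similar transcripts depend on the read assignment, which short reads settle only in part.

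Both sexes were represented in both pools. Xist, the RNA of the inactive X chromosome, stood at 28.8 and 23.1 TPM. Among Y-linked genes Eif2s3y stood at 20.5 and 23.4, Ddx3y at 15.7 and 17.7 and Uty at 7.76 and 6.88, and Kdm5d, the lowest detected, at 5.52 and 6.12. Usp9y at 0 and 0.010 (intervals up to 0.0138 and 0.0237), and Zfy1 and Zfy2 at 0 (intervals up to 0.0649 and 0.0696, and 0.0645 and 0.0689), were not detected. The ratio of Xist to summed Y-linked TPM was 0.584 and 0.428, a mean of 0.506 ± 0.110 (SD, n = 2). On scaled counts it was 3.14 and against Ddx3y alone 1.58, so its size holds only for the unit and genes used. Spike-in sequences held 2.14% and 2.37% of the estimated count, and 57 and 55 of 96 had 1 TPM or more.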

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

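No test in this part was chosen only after the result was seen, since none was run on these values. Reads were assigned to features that the comparisons above do not use, and their counts lie above the limit of 3 reads that a count of 0 allows. The short numbered features, which name no gene, held 71 estimated reads in replicate 1 and 66 in replicate 2, on 6 and 5 of 26248 features. The 884 Ensembl identifiers without a name in GENCODE M21 held 82008.52 estimated reads in replicate 1 and 73651.31 in replicate 2, or 0.203% and 0.201% of all.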

How the results depend on the processing

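The alternatives with posterior mean TPM for genes apart, with no rescaling of TPM for lists and with the genes apart left out of the coefficient of variation were chosen after seeing the data. The number of genes apart was between 38 and 42 under 5 alternatives (other or no scaling, pseudocount 1, the length trend removed, posterior mean TPM), with 38 to 40 of the 40 genes kept. It was 320 without a filter and 157 with a mean of 1 TPM, where more genes could enter, and 62 with the exact binomial test in place of the intervals. Each of these held all 40. The 20 genes named by ratio kept their direction under 4 alternatives. The Pearson r was 0.968 with a pseudocount of 0.1, 0.940 with 0.01, 0.993 without a filter and 0.994 with posterior mean TPM. The SD of the log2 ratio over all genes was 0.65 without a filter against 0.39 with it, as low genes enter. The coefficient of variation was 0.0746 with DESeq2 size factors, 0.0845 without a filter and 0.0596 without the genes apart; the DESeq2 median of 1e-04 per gene is the bottom of that tool's range. The globin share was 1.41% of the count, the spike-in share 4.98% of the TPM, and the ratio of Xist to Y-linked genes 3.14 on counts and 1.58 against Ddx3y alone, since these measure other quantities. Genes led by an isoform were 22.9% at 90% of the TPM, 34.2% at a mean of 1 TPM, 33.7% with posterior means and 38.3% to 39.2% with a replicate left out, where a single library has to pass. Leading isoforms differed for 386 genes by point estimates and 0 by intervals. The mitochondrial list had a median log2 ratio of 0.00219 that turned to -0.0276 with the length trend removed and -0.0693 without rescaling; the cause was not tested. Among lists inside the random range, basement membrane, BMP and TGF-beta, hedgehog and insulin-like growth factor genes changed sign near 0 with the length trend removed, and cartilage genes with all members, each staying inside. Without rescaling further lists inside the range changed sign, as the TMM shift no longer raised replicate 2. Shifts outside the range otherwise kept their direction, with 20 to 22 lists outside under 5 alternatives. Detected genes ranged from 11012 at 5 TPM to 19826 at 0.1 TPM. No paired analysis was possible because the series has a single group.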

Other observations

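The tests of a single heart tissue, of reads from other libraries and of a smaller share of epithelium were chosen only after the result was seen, as was the rule that a bootstrap interval must clear the limit of random lists. RNAs of genes listed as lacking a poly(A) tail were present. The values do not show whether the molecules sequenced carried a tail. Of 67 replication-dependent histone genes, which serve DNA replication, 56 were detected with a median of 6.83 ± 0.481 TPM, led by Hist1h2ap at 3684 ± 232, Hist1h4d at 497 ± 35 and Hist1h2ae at 269 ± 23.2. The 7 polyadenylated histone genes had a median of 465 ± 16.4, with H3f3a at 2090.4 ± 84.5, H2afz at 1909 ± 60.7, H3f3b at 1598 ± 33.2 and H2afy lowest at 269 ± 3.62. In the fixed list of noncoding RNAs taken to lack a tail, which takes in no 7SL RNA, Malat1 led. It was followed by Rn7sk at 254 ± 8.86, Rpph1 at 89.6 ± 4.74 and Neat1 at 10.7 ± 1.79. The telomerase RNA Terc lay under the minimum at 0.485 ± 0.0212. In the list of mitochondrial mRNAs, mt-Atp6 stood at 6009 ± 108, mt-Atp8 at 4338 ± 77.3 and mt-Cytb at 2329 ± 68.2, without the reads assigned to nuclear pseudogenes, so their order is uncertain. mt-Nd4l, which overlaps mt-Nd4, stood at 0 and 54.9 (intervals up to 64.6 and 155).

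Genes of stress and of organ function were present too. Hypoxia genes were all 10 detected at a median of 53.3 ± 3.66 TPM, with Ldha at 1593 ± 58.4, Pgk1 at 236 ± 1.47, Bnip3 at 96.3 ± 5.76 and Car9 lowest at 4.56 ± 0.891. Immediate early genes had 10 of 11 detected and a median of 15.7 ± 1.85, with Jun at 104 ± 0.94, Btg2 at 95 ± 2.57 and Ier2 at 77.1 ± 0.919, while Fos stood at 4.63 ± 0.205 and Fosb lay under the minimum at 0.16 ± 0.0424. The 8 glucocorticoid genes were detected at a median of 23.5 ± 3.03, with the target Tsc22d3 at 90.2 ± 5.47, the receptor Nr3c1 at 62.9 ± 2.12, Sgk1 at 37.4 ± 3.39 and Hsd11b2 lowest at 2.3 ± 0.099. Of ion and fluid transport genes 9 of 10 were detected at a median of 11.1 ± 0.233, with Atp1b1 at 75.4 ± 10.6 and the chloride channel Ano1 at 69.4 ± 8.68.

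Genes listed for neighbouring organs differed between the pools, and small amounts of those organs in the dissected lungs are a candidate explanation. Which cells expressed the listed genes here, the cardiomyocyte genes among them, was not tested. Among 18 further liver genes, 17 had 10 or more reads over both libraries and all 17 were higher in replicate 2 after TMM scaling, with a median log2 ratio of 2.24 (bootstrap 1.18 to 2.80); 13 of 13 further T cell genes were lower there, with a median of -1.70 (-2.28 to -1.36). The most abundant member of each list differed least: Hp had 25.1 TPM in both libraries, and Tcf7 had 44.4 and 34.6. Of these lists, 5 of 18 liver genes and 3 of 13 T cell genes also had 1 TPM or more in the library with less. The tables argue against a length trend, since 39 of 40 genes stayed 2-fold apart without it. The trend was small: its removal changed the log2 ratio by a median of 0.012 over genes with a mean of 1 TPM or more. Genes picked for a 2-fold difference could thus hardly fall below it. More of a single heart tissue in replicate 1 stays open: 3 genes of ventricular muscle had a median of 1.85 and atrial genes -1.06, but skeletal muscle expresses those 3 too and its list also lay higher in replicate 2, and most of these genes were picked because they lay apart. Reads from other tissue libraries cannot be told apart from tissue in the sample, because gene values such as the 11 genes apart on organ lists look alike under both. A biological explanation was not tested.

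Alveolar genes were lower in replicate 2, and an earlier stage of that pool may explain it. Late maturation genes chosen before their values were seen also lay lower, with a median of -0.19 over 16 genes (random lists -0.03 to 0.08). The bootstrap interval, over resampled genes and not pools, was -0.30 to -0.08. These genes may mark the same cells as the alveolar lists and then fall with them under any cause. Their fall therefore cannot tell an earlier stage from another cause. For early genes the outcome set down in advance for another cause was met by the median: 4 genes had 0.11, inside the range of random lists (-0.19 to 0.15). Their bootstrap interval of 0.07 to 0.22 crosses that limit, so these 4 genes leave the question open. The 18 alveolar genes lay lower than 20 general epithelial and tip genes, with a difference of -0.25 (-0.39 to -0.15). This comparison was chosen after the list medians were seen. The airway (-0.17) and neuroendocrine (-0.40) lists, left out of it, also lay lower, so a smaller share of epithelium stays open. A length trend is argued against, since the alveolar median was -0.26 both with and without it. The trend was small beside that median, as its removal changed the log2 ratio by a median of 0.012. Both pools carry the same age label, so stage within that age stays an open hypothesis.

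Pseudogenes of chromosome 1, named here after their values were seen, ranked among the most abundant features: Gm28437 at 7156 ± 238 TPM, Gm28661 at 2474 ± 193 and Gm29216 at 2251 ± 90.4. Reads shared with mitochondrial transcripts are a candidate explanation. Gm28437 matched mt-Co3 and Gm28661 mt-Co2 over 100% of their length, and Gm29216 matched mt-Co1 over 98.2%, each at 98% identity or more. The levels of mt-Co1, mt-Co2 and mt-Co3 are then too low by an unknown amount. No biological explanation was tested.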
